A study of Mus musculus with 18 samples.

How the data were processed

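RNA was measured in islets isolated from C57BL/6 mice in 18 libraries, 3 for each of 6 groups made by genotype (exon 2 of Cdh13 deleted, or flanked by loxP sites), age (8 or 14 weeks) and diet (chow, or 6 weeks of high-fat diet up to 14 weeks). Per the labels, total RNA was extracted with a miRNeasy kit, cDNA was made with SMART-Seq HT and libraries with Nextera, a preparation that does not mark the strand. The authors deposited 1 table of gene-level FPKM per library, made, per the submitters' processing notes, with TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mouse build mm10; the roles of the aligners, the annotation and any trimming or filtering are not given in the sources used here. The unit is not named in the labels or headers and was taken from Cufflinks and from the values. The deposited FPKM values look rescaled between libraries, since the median ratio of each library to the geometric mean library lay between 1.0037 and 1.0079 while the sums differed by 1.54 times. Reads were not analysed here.

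Each table listed 24346 gene symbols, of which 5544 were at 0 in every library; 23143 symbols matched the annotation used for positions and 1099 more matched a synonym. Genes with at least 1 FPKM in at least 3 of 18 libraries were kept (12234), and log2(FPKM + 1) was modelled with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 6 group means and moderated variances that follow a trend and are robust to outlying genes. The 12 contrasts were deleted against floxed in each condition and over their mean, high-fat diet against chow in each genotype and over their mean, 14 against 8 weeks likewise, and the interactions of genotype with diet and with age. P-values were adjusted over the tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Sets were tested with camera, the competitive test of limma, with a preset correlation of 0.01 and with a correlation estimated from the data, for 31 gene lists, of which 29 had at least 3 tested members; the adipocyte list had 1 tested member and the mitochondrially encoded list had 0 measured members. Single genes followed in every library were compared by exact permutation. The number of fragments per library is unknown. The precision of each library was judged from the commonest ratio of its low values to those of a reference library. Only a narrow range of ratios was searched, and the estimates spanned 1.38 times between libraries, so larger differences could not have been found. Tested on simulated data on 12077 genes, the same model recovered 59.7% of genes changed by 0.5 on the log2 scale on the high-fat diet and 95.5% of those changed by 1, with 6 false calls, and 91.0% and 97.0% over the mean of the 3 conditions, with 9 false calls. The simulated noise was independent between genes, so these figures do not cover errors that genes of a library share.

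The model, lists, thresholds, alternatives and rule for naming genes were chosen before the data were examined. Named in every contrast were Cdh13, Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Pdx1, Ucn3 and Slc2a2; in each contrast, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (not required for interactions), the 5 smallest p-values where fewer than 5 genes were called, and up to 4 members with the smallest p of each called list. Some genes that met this rule are not reported here. Mafa was at 0.83 on the high-fat diet between genotypes (adjusted p = 0.0997). The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, sample quality weights, only the groups compared in the fit, the replicate number as a block, the mean of the acinar markers as a covariate, the estimated correlation for lists, and each of the 18 libraries left out in turn. Where a library was left out, the group of 2 was assumed to vary like the others. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.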

Results

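Islets of Langerhans, the endocrine cell clusters of the pancreas, were profiled by RNA sequencing in C57BL/6 mice that lacked exon 2 of Cdh13 (deleted) and in mice that carried the intact exon between loxP sites (floxed). Cdh13 encodes T-cadherin, a cell surface cadherin that binds adiponectin. The 18 libraries formed 6 groups of 3, with each genotype at 8 weeks of age on chow, at 14 weeks on chow, and at 14 weeks after 6 weeks on a high-fat diet. The values were gene-level FPKM under gene symbols, and 12234 of 24346 listed genes were tested. Read totals were not analysed here, so the absolute depth of each library is unknown. Summed FPKM ranged from 903346 to 1394010 per library. The estimated relative value of a single fragment spanned 1.38 times between libraries, within a narrow range searched, which does not exclude larger differences. Between 11474 and 11787 genes reached 1 FPKM in each library. The insulin gene Ins2 held between 40.2% and 52.7% of the summed FPKM, and the 10 most abundant genes together held between 55.7% and 67.8%. Pearson's r across genes was 0.981 to 0.991 for the 18 pairs of libraries within groups and 0.963 to 0.990 for the 135 pairs between groups. The labels number the replicates but do not say that each came from a separate animal, so each p measures only the spread between these samples. Changes are given as differences of log2(FPKM + 1), a scale that understates the fold change of genes at low FPKM, and adjusted p-values are from limma. Interactions apart, rises and falls named as large or largest were chosen among called genes whose groups did not overlap in any condition or genotype averaged, so other called genes can exceed them.

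Cdh13 itself was low in every group and lower in deleted than in floxed islets in each condition, with no overlap between the genotypes. At 8 weeks it measured 1.34 ± 0.433 FPKM in floxed and 0.632 ± 0.242 FPKM in deleted libraries (mean ± SD, n = 3 each), so the deleted level was 47.3% ± 13.7 (SE) of the floxed level. At 14 weeks on chow the means were 1.67 ± 0.366 and 0.551 ± 0.136 FPKM, and the deleted level was 33.0% ± 6.28 of the floxed level. On the high-fat diet they were 1.33 ± 0.141 and 0.456 ± 0.308 FPKM, or 34.4% ± 13.6. The log2 differences were -0.51 (adjusted p = 0.179), -0.78 (adjusted p = 0.0674) and -0.69 (adjusted p = 0.0107) in the order given, and -0.66 over the 3 conditions (SE 0.0968, adjusted p = 5.91e-04). Neither diet (-0.19, adjusted p = 0.417 in floxed; -0.11, 0.722 in deleted; -0.15, 0.344 over both) nor age (0.20, 0.594; -0.07, 0.905; 0.07, 0.787) passed for it, and the interactions of genotype with diet (0.09, 0.903) and age (-0.27, 0.829) did not pass. An exact permutation test gave p = 0.1 in each condition, the smallest that 3 against 3 allows, and p = 2.5e-04 with genotype permuted within the 3 conditions, the smallest of 8000 arrangements. The gene spans 118140017 to 119324929 on chromosome 8 (mm10), and exon 2, at 118505604 to 118505715, makes up 112 of 3785 bases of summed exon length, so these values count fragments over 14 exons and not over the deleted exon alone. Without replicate 1 of the deleted high-fat diet libraries the difference on that diet was -0.59 and no longer passed (adjusted p = 0.0615). With sample quality weights the difference at 14 weeks on chow was -0.77 and passed (adjusted p = 0.025, against a range of 0.025 to 0.344 over its alternatives).

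A pair of genes on chromosome 19 was lower in deleted islets in all 3 genotype comparisons. Ide, which encodes the insulin-degrading enzyme (37268743 to 37334544), measured 48.9 ± 1.02 FPKM in floxed and 26.4 ± 1.23 FPKM in deleted libraries at 8 weeks (mean ± SD, n = 3 each). It measured 49.7 ± 2.13 and 25.1 ± 0.633 at 14 weeks on chow, and 51.5 ± 2.72 and 25.8 ± 0.494 on the high-fat diet. Its deleted level was therefore 54.0% ± 1.59 (SE) of the floxed level at 8 weeks and 50.5% ± 1.45 at 14 weeks on chow, and its log2 difference over the 3 conditions was -0.93 (SE 0.0343, adjusted p = 7.21e-13). Fgfbp3, which encodes a carrier protein for fibroblast growth factors (36917550 to 36919599), was at 34.1% ± 7.78, 44.9% ± 5.75 and 47.8% ± 3.29 of its floxed level in the 3 conditions. Its log2 difference over the conditions was -1.02 (SE 0.0935, adjusted p = 6.27e-06). Of the 3 tested genes between them, chosen after their values were seen, Btaf1 was at -0.36 over the 3 conditions (adjusted p = 0.00222), Cpeb3 at -0.13 (adjusted p = 0.301) and March5 at -0.06 (adjusted p = 0.309). The only other gene called in all 3 comparisons was Ppap2a, a lipid phosphatase gene, which rose by 0.44 at 8 weeks and fell by 0.50 at 14 weeks on chow and by 0.37 on the high-fat diet. Without overlap between genotypes in any condition, 24 genes were lower and 14 were higher in deleted libraries, where chance gives 1.53 in each direction. At 14 weeks on chow the calls of Fgfbp3 and Ppap2a ended with no filter on low values, with only the groups compared in the fit, and when replicate 1 or 3 of the deleted group or replicate 2 or 3 of the floxed group was left out. The call of Ide held in every alternative.

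**Figure D1:**
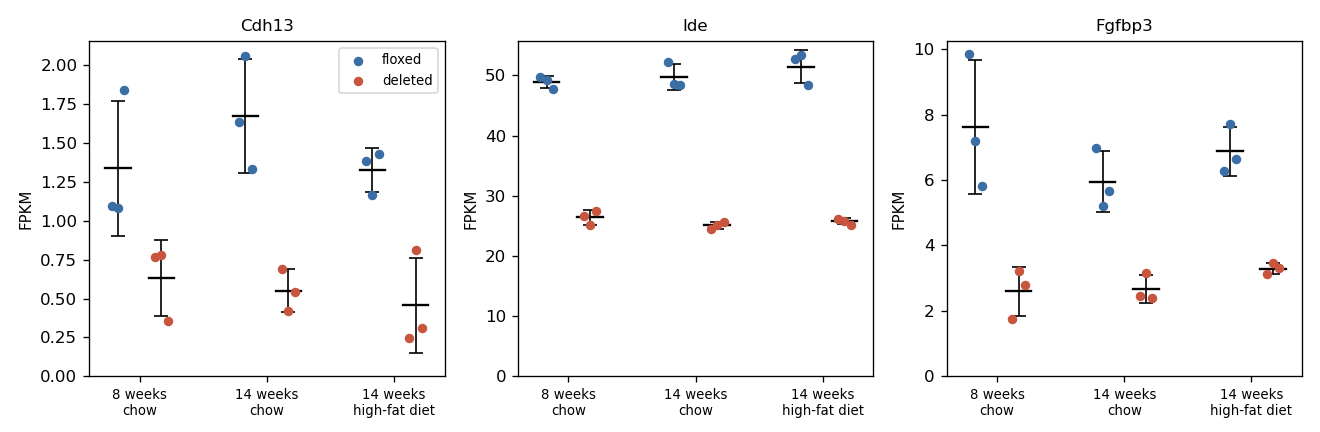
Level of Cdh13, Ide and Fgfbp3 (y axis, FPKM) in floxed and deleted islets at 8 weeks on chow, 14 weeks on chow and 14 weeks on the high-fat diet (x axis); points are libraries and bars are mean ± SD of 3. Ide sits near 50 FPKM in floxed and near 26 FPKM in deleted libraries in each condition.

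The genotype comparisons differed in how many genes passed. Deleted and floxed islets differed at 67 genes at 8 weeks, 14 at 14 weeks on chow and 1312 on the high-fat diet, and the diet and age comparisons ranged from 356 to 4236. Across genes, which are not independent replicates, the genotype effect at 8 weeks had r = 0.129 (rho = 0.0369) with that at 14 weeks on chow and r = -0.0330 (rho = -0.0157) with that on the high-fat diet. The effects at 14 weeks on chow and on the high-fat diet had r = 0.0374 (rho = 0.0474). Between 8 weeks and the high-fat diet, 5 genes were higher in both comparisons where 1.03 would be shared by chance. Between them 8 were lower in both where 2.71 would be, and 5 were called in opposite directions, without a chance value for these. The 8-week and 14-week chow comparisons shared 1 higher gene (0.0144 by chance) and 2 lower (0.0221), with 1 opposite. The 14-week chow and high-fat diet comparisons shared 2 higher (0.376) and 3 lower (0.361), with 2 opposite. Among the gene lists fixed for this tissue, no comparison called the cadherins and catenins, the adiponectin and lipoprotein receptors, the serotonin, prolactin receptor and growth genes, the lymphocyte markers or the Schwann cell and neuronal markers.

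**Figure D2:**
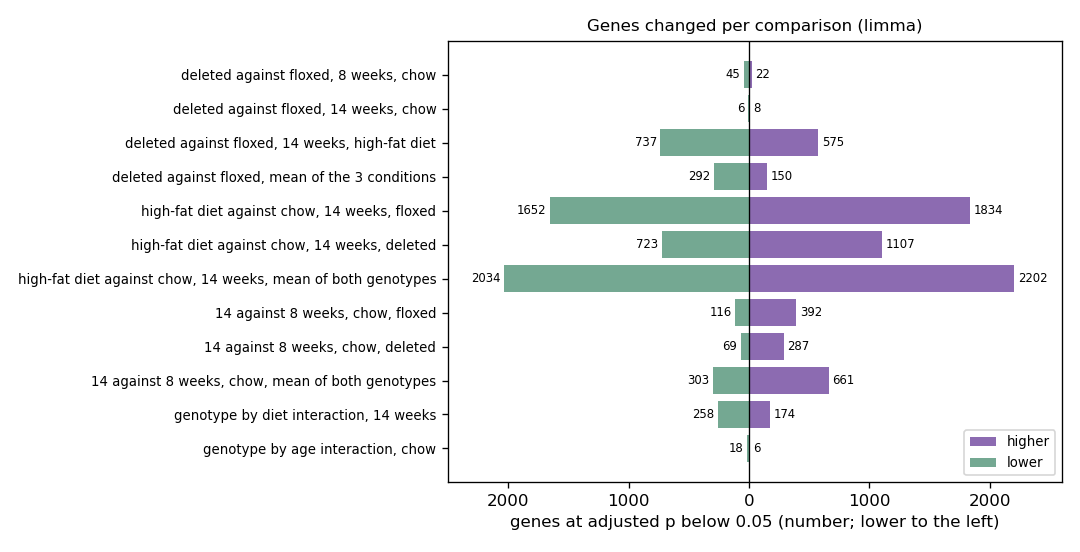
Number of genes with adjusted p below 0.05 (x axis, lower to the left) that were higher or lower in each of the 12 comparisons (y axis) of 18 libraries. Deleted and floxed islets differed at 1312 genes on the high-fat diet (575 higher, 737 lower), against 67 at 8 weeks and 14 at 14 weeks on chow.

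At 8 weeks on chow, deleted islets held less glucagon transcript and more of the gut and islet hormone peptide YY, though both calls ended in several alternatives given below. Gcg, the glucagon gene of alpha cells, fell by 0.65 on the log2 scale (SE 0.122, adjusted p = 0.0175, n = 3 against 3), and Pyy rose by 0.86 (SE 0.169, adjusted p = 0.0341). Ppy, the pancreatic polypeptide gene, averaged 39704 ± 6108 FPKM in deleted and 9830 ± 2517 FPKM in floxed libraries but did not pass (log2 2.04, adjusted p = 0.0710). The insulin genes Ins1 (-0.02, adjusted p = 0.957) and Ins2 (-0.02, adjusted p = 0.956) did not pass. The largest fall was that of Erdr1, a gene placed on chromosome X in the annotation (170010526 to 170018797), from 63.8 ± 18.7 to 5.65 ± 0.408 FPKM (log2 -3.25, SE 0.261, adjusted p = 3.93e-05). Other falls among the largest were those of Nptxr, a neuronal pentraxin receptor gene (-1.37), the microfibril gene Mfap2 (-1.18) and the gluconeogenic enzyme gene Fbp1 (-0.84). The Wnt pathway scaffold gene Axin1 (-0.82), Narf (-0.81), B930041F14Rik (-0.81) and the phosphatase gene Pdxp (-0.81) also fell. Among the largest rises were those of the fibrinogen chain gene Fgb (1.82) and of the glucuronosyltransferase genes Ugt2b35 (1.31) and Ugt2b36 (0.81). The tetraspanin gene Tspan8 (0.81), the folate receptor gene Folr1 (0.80), the interferon-induced GTPase gene Gbp11 (0.80), S100a6 (0.80) and Wfdc17 (0.78) rose as well.

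By group, the glycolysis genes lay lower in deleted islets at 8 weeks by a set test with a preset correlation, a call that did not hold with an estimated one (adjusted p = 0.376). Their median log2 difference was -0.24 over 15 tested members, of which 0 passed over all genes and 7 fell when adjusted over the list alone. The aldolase gene Aldoa was at -0.43 (adjusted p = 0.0595 over all genes) and the phosphofructokinase gene Pfkl at -0.90 (adjusted p = 0.0636). Of 7 alpha cell markers, 1 fell over all genes and 4 fell when adjusted over the list alone, with the transporter gene Slc38a5 at -0.94 and the transcription factor gene Irx2 at -0.56. Among inflammatory cytokines and chemokines none of 16 passed over all genes and 4 rose when adjusted over the list alone, with the chemokine genes Ccl2 at 1.26 and Cxcl1 at 0.82. That test, camera, called 12 of 29 lists and none with an estimated correlation, where the adjusted p was 0.155 for both alpha cell markers and inflammatory genes. The other 9 calls were beta cell identity, lower (adjusted p = 0.376 with an estimated correlation), and, higher, 8 others. These were endothelial (0.376), macrophage (0.376), delta and PP cell (0.376), erythroid (0.155), immediate early (0.397), extracellular matrix (0.431), ribosomal protein (0.794) and acinar genes (0.781). The delta and PP cell list was called higher although its median was -0.01. Acinar marker transcripts made up 0.0734% ± 0.0908 of summed FPKM in deleted and 0.0214% ± 0.0102 in floxed libraries (mean ± SD, n = 3), and replicate 1 of the deleted group alone held 0.177%. Without that library the acinar and ribosomal lists had medians of -0.09 and -0.02. The glycolysis median was -0.15 without replicate 3 of the floxed group, which had the highest mean of that list of the 6 libraries, and the call held. Without replicate 1 of the floxed group the calls of 9 of the 12 lists ended, those of glycolysis, alpha cell and inflammatory genes excepted.

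Of the 67 genes that passed at 8 weeks, 22 were higher and 45 lower (32.8% higher, or 43.3% with quantile normalization), and 1535 genes had an unadjusted p below 0.05. The count was 25 with no filter on low values, 44 with only these groups in the fit and 406 with sample quality weights. The calls of Gcg, Pyy, Tspan8, Folr1, S100a6, Fbp1, Gbp11 and Axin1 ended with no filter. The count was 16 and 28 without replicates 2 and 3 of the floxed group, 32 and 25 without replicates 1 and 2 of the deleted group, and 168 without replicate 3 of the deleted 14-week chow group. The call of Gcg ended without replicate 1 or 2 of either 8-week group, and that of Pyy without any of the 6 libraries of 8 weeks and with quantile normalization, where it was at 0.44. With only these groups in the fit the calls of Gcg, Ugt2b36, Gbp11, Nptxr and Fbp1 ended, with a pseudocount of 0.1 that of Gbp11 and with the acinar covariate that of Folr1.

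At 14 weeks on chow, deleted islets differed from floxed islets at few genes, and the endocrine hormone genes did not pass. Star, which encodes the protein that carries cholesterol into mitochondria for steroid synthesis, rose by 1.15 (SE 0.111, adjusted p = 1.43e-05, n = 3 against 3). The other rises were those of the calcium-binding protein gene Rgn (0.64), the ectonucleotidase gene Entpd2 (0.58) and the stress-induced regulator Nupr1 (0.58). The adenosine receptor gene Adora2b (0.53), the sphingolipid enzyme gene Degs2 (0.43), the transaminase gene Gpt2 (0.40) and the creatine kinase gene Ckb (0.40) rose too. Besides Ide (-0.96) and Fgfbp3 (-0.92), the receptor gene Lrp3 fell by 0.90, the G protein signalling regulator Rgs1 fell by 0.80, Ppap2a fell by 0.50 and the lysosomal protease gene Ctss fell by 0.45. Gcg was at -0.25 (adjusted p = 0.643), Sst, the somatostatin gene of delta cells, at -0.38 (adjusted p = 0.157) and Ins2 at 0.02.

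The gene groups of this comparison moved without members that passed over all genes. Camera called 14 of 29 lists, 12 of them lower, and only the macrophage markers held with an estimated correlation (adjusted p = 0.0179). Of these, 3 of 12 fell when adjusted over the list alone, with Cd14 at -0.93 and the complement gene C1qb at -0.45. Adjusted over the list alone, 6 of 13 endothelial markers fell (adjusted p = 0.0848 with an estimated correlation), as did 6 of 15 glycolysis genes (0.203), 4 of 15 type I interferon genes (0.183) and 4 of 16 inflammatory genes (0.0848). Examples were the endothelial adhesion gene Esam (-0.36, adjusted p = 0.149 over all genes), the glycolytic gene Ldha (-0.60, 0.375), the antiviral gene Rsad2 (-0.76, 0.212) and Icam1 (-0.55, 0.240). The other lower lists were extracellular matrix (0.183 with an estimated correlation), Notch (0.0848), fibroblast (0.258), duct (0.164), delta and PP cell (0.203), immediate early (0.164) and disallowed genes (0.164). The unfolded protein response (0.183) and erythroid genes (0.164) lay higher. Acinar markers made up 0.321% ± 0.0878 of summed FPKM in deleted and 0.427% ± 0.336 in floxed libraries (mean ± SD, n = 3), the highest shares of the 6 groups. The calls of the erythroid, interferon, fibroblast, disallowed and delta and PP cell lists ended without replicate 2 of the floxed group, and that of the duct list without its replicate 1. A mean of at least 5 FPKM, which leaves fewer members, ended the duct, interferon, inflammatory and Notch calls, with the Notch median at 0.0123.

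Of the 14 genes, 8 were higher and 6 lower (57.1% higher, or 40.7% of 27 genes with quantile normalization), and 976 genes had an unadjusted p below 0.05. The calls of Gpt2, Fgfbp3, Lrp3, Rgs1, Ppap2a and Ctss ended with no filter on low values, that of Rgs1 with a pseudocount of 0.1 and that of Nupr1 with quantile normalization, and those of Ide and Star alone held with only these groups in the fit. The count was 25 with a mean of at least 5 FPKM required, 114 with sample quality weights and 2 with only these groups in the fit. It was 3 and 7 without replicates 2 and 3 of the floxed group, and 9, 9 and 7 without replicates 1, 2 and 3 of the deleted group. It was 30, 9 and 23 without replicates 1, 2 and 3 of the deleted 8-week group.

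On the high-fat diet, deleted islets held more transcript of beta cell genes and less of cell cycle genes than floxed islets. Camera called 11 of 29 lists, and of these the beta cell and cell cycle lists alone held with an estimated correlation. Slc2a2, which encodes the glucose transporter GLUT2, rose from 25.3 ± 2.49 FPKM in floxed to 53.6 ± 5.87 FPKM in deleted libraries (mean ± SD, n = 3 each; log2 1.05, SE 0.0922, adjusted p = 6.77e-07). Pdx1, the transcription factor that maintains beta cells, rose from 19.3 ± 1.04 to 29.6 ± 1.68 FPKM (0.59, adjusted p = 2.29e-04). Sst rose from 1501 ± 78.2 to 2707 ± 182 FPKM (0.85, adjusted p = 1.84e-05) and Gcg rose by 0.71 (adjusted p = 8.50e-04). Ins1 was at 0.24 (adjusted p = 0.127) and Ins2 at -0.05 (adjusted p = 0.824). Ube2c, a ubiquitin ligase subunit gene of mitosis, fell from 5.96 ± 2.82 to 0.958 ± 0.494 FPKM (-1.77, adjusted p = 3.12e-04). The interferon-induced gene Rsad2 fell from 8.17 ± 2.90 to 1.81 ± 0.189 FPKM (-1.65, adjusted p = 6.34e-05).

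Beta cell identity and function genes rose as a group on this diet. Of 24 members, 11 rose, none fell and the others did not pass. Of the 24, 17 rose when adjusted over the list alone, with the granule protein gene Sytl4 (0.66) and the prohormone convertase gene Pcsk2 (0.34) among them. The list's adjusted p was 1.44e-08, or 0.0192 with an estimated correlation. Of 5 delta and PP cell markers, 3 rose, over all genes and adjusted over the list alone. These were Sst, the retinol-binding protein gene Rbp4 (1.12) and the delta cell transcription factor Hhex (0.98; adjusted p = 0.116 for the list with an estimated correlation). Of 7 alpha cell markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone). Irx2 was at 0.80, the amino acid transporter gene Slc7a2 at 0.42 and Gc, the vitamin D-binding protein gene, at -1.05 (adjusted p = 0.293 with an estimated correlation). Of 18 oxidative stress genes, 7 rose (9 rose and 1 fell adjusted over the list alone). Among them were the metallothionein gene Mt2 (0.81), the glutathione peroxidase gene Gpx3 (0.60), Srxn1 (0.49) and Gclc (0.45; adjusted p = 0.116 with an estimated correlation).

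Cell cycle genes fell as a group. Of 14 members, 7 fell, 8 adjusted over the list alone, among them the cyclin-dependent kinase gene Cdk1 (-0.98), Cdc20 (-1.16) and the cyclin gene Ccnb1 (-0.76). Cdk1 and Ccnb1 reached 1 FPKM in the floxed high-fat diet libraries alone, so the filter kept them only through the group where they were high. Leaving out any of those libraries left 11 tested members. The list held with an estimated correlation (adjusted p = 0.0192). Of 15 type I interferon genes, 8 fell (9 adjusted over the list alone), including Ifit1 (-1.06; adjusted p = 0.168 with an estimated correlation). Of 13 endothelial markers, 7 fell (9 adjusted over the list alone), including Esam (-0.56), the angiopoietin receptor family gene Tie1 (-0.73) and VE-cadherin, Cdh5 (-0.56; adjusted p = 0.116 with an estimated correlation). Of 15 glycolysis genes, 7 fell (9 adjusted over the list alone), including Aldoa (-0.50) and Tpi1 (-0.66; adjusted p = 0.328 with an estimated correlation). Of 20 extracellular matrix genes, 4 fell (8 adjusted over the list alone), including the matrix genes Sparc (-0.80) and Postn (-1.10; adjusted p = 0.322 with an estimated correlation). The hemoglobin genes Hbb-b1 (-1.51) and Hba-a1 (-1.29) were among 3 of 4 erythroid markers that fell, over all genes and adjusted over the list alone (adjusted p = 0.0609 with an estimated correlation). Of the other types, 1 of 10 fibroblast markers, the receptor gene Pdgfrb (-0.67), fell (5 adjusted over the list alone; 0.367 with an estimated correlation). Acinar markers made up 0.0180% ± 0.00742 of summed FPKM in deleted and 0.0198% ± 0.0187 in floxed libraries (mean ± SD, n = 3).

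The largest rises outside these lists were those of the guanylin gene Guca2a (1.61), the imprinted neuronatin gene Nnat (1.46), Smim24 (1.35), Ugt2b35 (1.19), the xenobiotic-metabolizing cytochrome gene Cyp1a1 (1.11), Klk14 (1.07), 2200002J24Rik (1.05) and Tmsb15l (0.99). The largest falls included those of Xlr4a (-1.70), Dapl1 (-1.68), the growth factor-binding gene Igfbp3 (-1.49), the apelin receptor gene Aplnr (-1.45), the vascular potassium channel gene Kcnj8 (-1.45) and Sparcl1 (-1.42). In all, 575 genes rose and 737 fell, 60 of them by more than 2-fold. The count was 820 without replicate 1 of the deleted group and 833 without replicate 3 of the floxed group. The median of the glycolysis list was -0.50, and -0.33 without replicate 2 of the floxed group. The calls of Pdgfrb ended with no filter and of Hba-a1 with only these groups in the fit. With quantile normalization Gcg no longer passed and the alpha cell call ended. A mean of at least 5 FPKM, which leaves fewer members, ended the calls of the alpha cell, cell cycle and interferon lists. The fibroblast call ended without replicate 3 of the floxed group, and that of Hbb-b1 without it or replicate 2 or 3 of the deleted group.

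**Figure D3:**
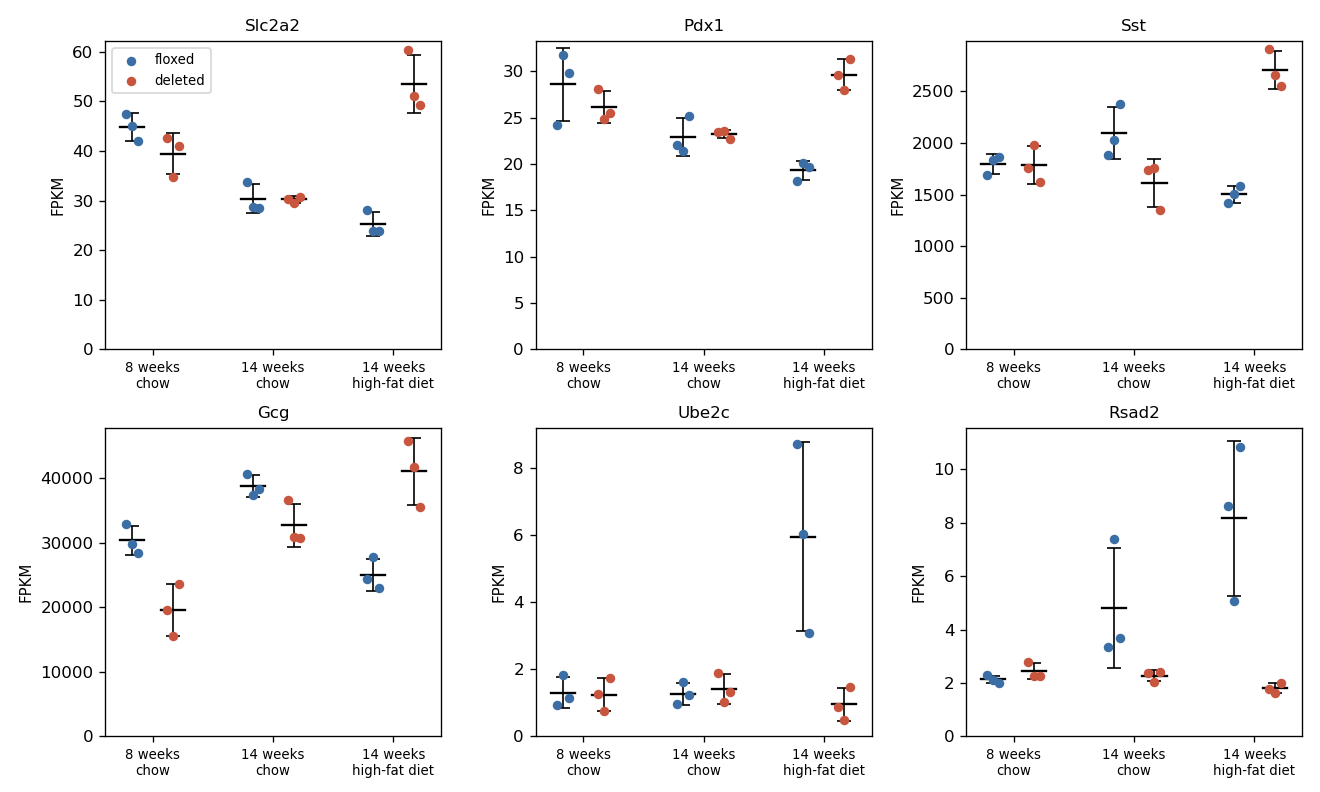
Level of Slc2a2, Pdx1, Sst, Gcg, Ube2c and Rsad2 (y axis, FPKM) in floxed and deleted islets in the 3 conditions (x axis); points are libraries and bars are mean ± SD of 3. On the high-fat diet Slc2a2 averaged 25.3 FPKM in floxed and 53.6 FPKM in deleted libraries, and Ube2c 5.96 and 0.958 FPKM.

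Averaged over the 3 conditions, deleted islets held less of glycolysis genes, besides Ide, Fgfbp3 and Cdh13, though no list call held with an estimated correlation. Of 15 glycolysis genes, 8 fell, none rose, and 12 fell when adjusted over the list alone (median -0.36, adjusted p = 1.13e-11, or 0.202 with an estimated correlation). Among them were Pfkl (-0.65, SE 0.116), Tpi1 (-0.49), Gpi1 (-0.46) and Aldoa (-0.42; 9 libraries against 9). Among genes without overlap between genotypes in any condition, the other large falls were those of Ankrd37, a gene induced by low oxygen (-0.95), the cell cycle regulator Cdk2ap1 (-0.57), the collagen prolyl hydroxylase gene P4ha1 (-0.55), Pdxp (-0.54) and the aldolase gene Aldoc (-0.48). Erdr1, which did not separate the genotypes in the same direction in every condition, was at -0.95 (adjusted p = 0.00379). Among genes without overlap the rises were smaller, led by the lysophospholipid-producing enzyme gene Enpp2 (0.41), the kinase gene Plk3 (0.29), 1700066M21Rik (0.24) and Cyb5b (0.20). Also higher were Thumpd3 (0.19), 2010111I01Rik (0.18), Rnf20 (0.17), Api5 (0.16), the autophagy receptor gene Sqstm1 (0.14) and Ensa (0.11). Slc2a2 was higher by 0.29 (adjusted p = 0.00436), while Ins1 (0.04), Ins2 (-0.02), Gcg (-0.06) and Sst (0.15) did not pass.

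Among other groups averaged over the conditions, 5 of 18 oxidative stress genes rose, such as Nqo1 (0.48) and Mt2 (0.39; 6 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation). Of 15 interferon genes 5 fell, such as Rsad2 (-0.76; 6 adjusted over the list alone; 0.278 with an estimated correlation). Of 13 endothelial markers 4 fell, such as Egfl7 (-0.33; 6 adjusted over the list alone; 0.229). Notch genes fell at 2 of 17, the ligand gene Dll4 (-0.31) and its target Hey1 (-0.39; 2 adjusted over the list alone; 0.229). Beta cell identity genes rose at 3 of 24 (4 adjusted over the list alone; 0.229), and delta and PP cell markers rose at 1 of 5 (5 adjusted over the list alone; 0.202). The remaining calls, all lower, were the fibroblast (0.459), extracellular matrix (0.459) and cell cycle lists (0.202), with 1 member passing in each. Of 442 genes, 150 were higher and 292 lower, and 10 lists were called. With sample quality weights the count was 906. With no filter the calls of 1700066M21Rik, Rnf20, Hey1 and Sparc ended, and with the acinar covariate those of Rnf20 and Ensa. Quantile normalization ended the calls of the beta cell list and of Sparc, Cdh5, Mt1 and Sqstm1, and a mean of at least 5 FPKM ended those of the Notch, cell cycle and interferon lists. The Notch call also ended when replicate 1 of the deleted 8-week, replicate 2 of the deleted or floxed 14-week chow, replicate 1 of the deleted high-fat diet or replicate 3 of the floxed high-fat diet group was left out.

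The high-fat diet was compared with chow at 14 weeks to describe how islets of each genotype differed between the diets. In floxed islets, Ins2 rose by 0.81 (SE 0.0982, adjusted p = 9.12e-06, n = 3 against 3) and Ins1 by 0.44 (adjusted p = 0.00233). Gcg fell by 0.63 and Sst fell by 0.48 (adjusted p = 7.73e-04 and 0.00163). The transcripts of cytotoxic lymphocytes Ifng (adjusted p = 1.58e-15), Gzmb and Gzmc, listed at 0 in every chow library, were present in every library on the diet. Transcripts of acinar cells, such as those of the trypsinogen gene Try4 (-5.42, adjusted p = 0.00574), Reg1 (-4.95), Cela2a (-4.63), the lipase gene Pnlip (-4.62) and Ctrb1 (-4.57), fell. Fatty acid oxidation genes and PPAR targets rose at 10 of 18 members, with 1 lower and the same counts adjusted over the list alone. They included the carnitine shuttle genes Slc25a20 (0.89) and Cpt1a (0.78) and Angptl4 (1.15; adjusted p = 0.0504 with an estimated correlation). Other large rises were those of the 45S ribosomal RNA gene Rn45s (2.41), the gluconeogenic enzyme gene Fbp2 (2.31), Dapl1 (2.13), the connexin gene Gjd2 (1.71), the calcium-binding protein gene Necab2 (1.71), 8430408G22Rik (1.70) and Mir703 (1.59).

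Among the lists in floxed islets, 20 of 23 acinar markers fell, 23 adjusted over the list alone (adjusted p = 0.384 with an estimated correlation). Their share of summed FPKM went from 0.427% ± 0.336 on chow to 0.0198% ± 0.0187 on the diet (mean ± SD, n = 3). Beside this, 5 of 7 duct markers fell, such as Krt19 (-1.84; the same adjusted over the list alone; 0.145 with an estimated correlation). The same held for 7 of 12 macrophage markers, such as Lyz2 (-1.28; the same adjusted over the list alone; 0.119). Ribosomal protein genes rose at 20 of 25 and fell at 1, with the same counts adjusted over the list alone (0.499), with Rps28 at 1.22. Oxidative stress genes rose at 11 of 18 and fell at 1 (12 and 2 adjusted over the list alone; 0.119), with Gpx1 at 0.74 and Sod1 at 0.69. Oxidative phosphorylation genes rose at 11 of 26 and fell at 2, over all genes and adjusted over the list alone (0.513). Cell cycle genes rose at 6 of 14 and fell at 1 (9 and 1 adjusted over the list alone; 0.287), with Ube2c at 1.54. Extracellular matrix genes (4 of 20 lower; 0.513), fibroblast markers (4 of 10 lower, 1 higher; 0.499) and disallowed genes (4 of 11 lower; 0.384) were also called lower. In all 1834 genes rose and 1652 fell. With the acinar marker mean as a covariate 1807 genes passed, 1609 of them shared with the 3486 and in the same direction. With that covariate the calls of Slc2a2 (-0.25), Cdk1, Cdc20, Mir703, the named acinar genes (Try4, Reg1, Cela2a, Pnlip and Ctrb1) and the cell cycle list ended. The calls of Slc2a2, Mir703 and Cela2a ended with no filter, as they and that of Pnlip did with only these groups in the fit. Quantile normalization, which gives Ins2 as the most abundant gene one value in every library, ended those of Ins1, Ins2, Gcg and the oxidative phosphorylation list. The cell cycle call also ended with a pseudocount of 0.1, and with a mean of at least 5 FPKM its median was 0.0271 and it ended. It ended too when replicate 1, 2 or 3 of the floxed high-fat diet group was left out, each of which left 11 tested members. The fibroblast call ended without replicate 1 of that group, and the duct call with a mean of at least 5 FPKM. The extracellular matrix and disallowed calls ended without replicate 1 or 2 of that group or replicate 2 of the floxed chow group, the disallowed call also without replicate 3 of the floxed chow group, with a pseudocount of 0.1 and with quantile normalization. A mean of at least 5 FPKM also ended the extracellular matrix call.

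Deleted islets held more transcript of insulin, Slc2a2 and Sst on the diet than on chow. Ins1 rose by 0.75 (SE 0.0964, adjusted p = 4.22e-05, n = 3 against 3), Ins2 by 0.74 (adjusted p = 6.07e-05), and Slc2a2 by 0.80 (adjusted p = 1.48e-05). Sst rose by 0.75 (adjusted p = 6.07e-05), Pdx1 by 0.34 (adjusted p = 0.0138) and Ucn3, a peptide gene of mature beta cells, by 0.25 (adjusted p = 0.0118). Of 24 beta cell identity genes 11 rose and none fell (12 adjusted over the list alone; adjusted p = 0.0155 with an estimated correlation). Of 18 oxidative stress genes 15 rose, over all genes and adjusted over the list alone, including Nqo1 (1.37), the thioredoxin-binding gene Txnip (0.92), Srxn1 (0.90) and Gclc (0.69; 0.00633 with an estimated correlation). Fatty acid oxidation genes rose at 7 of 18, the same adjusted over the list alone, such as Cpt1a (0.72; 0.0155). Falls were seen at 3 of 4 erythroid markers, such as Hba-a1 (-2.67; 0.0102). Besides Ifng, Gzmb and Gzmc, other large rises were those of Mbd2 (2.15), Znrf2 (2.09), Rn45s (2.04), Ybx3 (1.97), Ugt2b35 (1.94), Lrp3 (1.76) and Cyp1a1 (1.73). The largest falls were again those of acinar genes such as Pnlip (-4.41) and Gp2 (-3.84), with the neuropeptide gene Vip (-3.71).

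Of the remaining lists in deleted islets, 16 of 23 acinar markers fell, 23 adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). The acinar share went from 0.321% ± 0.0878 to 0.0180% ± 0.00742 of summed FPKM (mean ± SD, n = 3). Ribosomal protein genes rose at 21 of 25, the same adjusted over the list alone (0.229), and oxidative phosphorylation genes at 9 of 26 (11 adjusted over the list alone; 0.353). Rises were also seen for delta and PP cell markers at 2 of 5 (4; 0.178) and alpha cell markers at 3 of 7 (4; 0.229). Unfolded protein response genes fell at 8 of 24 and rose at 2 (14 and 2 adjusted over the list alone; 0.236), with the stress transcription factor Ddit3 at -0.50 and the chaperone gene Hspa5 at -0.29. Endothelial markers fell at 4 of 13 (0.178), extracellular matrix genes at 6 of 20 (0.229) and fibroblast markers at 6 of 10 with 1 higher (0.229). Lower too were macrophage markers at 2 of 12 (0.178), duct markers at 2 of 7 (0.178) and cell cycle genes at 2 of 14 (0.178). In all 1107 genes rose and 723 fell. The count was 1159 without replicate 3 of the deleted chow group, 1164 without replicate 2 of the deleted high-fat diet group and 2834 with sample quality weights. With the acinar covariate 761 passed, 673 shared in the same direction. That covariate ended the calls of Pdx1, Ybx3, Pnlip, Vip, Ddit3, Hspa5 and the unfolded protein and alpha cell lists, and quantile normalization ended those of Ins1, Ins2, Ucn3 and the oxidative phosphorylation, alpha cell and cell cycle lists. Pdx1 no longer passed without replicate 3 of either deleted group and Ucn3 without replicate 1 of the deleted chow group.

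Averaged over both genotypes, islets held more insulin and cytotoxic lymphocyte transcripts and less of those of exocrine cells on the high-fat diet than on chow. Ins2 rose by 0.77 (SE 0.0695, adjusted p = 1.40e-07, 6 libraries against 6), from 410310 ± 33924 to 715768 ± 17898 FPKM in floxed and from 418425 ± 54789 to 693373 ± 24241 FPKM in deleted islets (mean ± SD, n = 3 each). As a share of summed FPKM the change of Ins2 was smaller, from 41.4% ± 1.17 to 52.2% ± 0.511 in floxed and from 42.1% ± 1.82 to 50.8% ± 0.744 in deleted islets. Ins1 rose by 0.60 (adjusted p = 2.45e-06). Ifng, which encodes interferon gamma, was listed at 0 in all 12 chow libraries and at 11.2 to 17.5 FPKM in the 6 high-fat diet libraries. Gzmb, a granzyme gene, was listed at 0 and 4.77 to 11.5, and Gzmc at 0 and 2.07 to 6.09. Counted after these values were seen, 11 genes were listed at 0 in all 12 chow libraries and above 0 in all 6 high-fat diet libraries. The others were Gzma, Gzmd, Gzme, Prf1, Xcl1, Klre1, Icos and Fasl. No gene had the opposite pattern. The same count was 0 for the 6 libraries of 14 weeks on chow and 0 for the 6 of 8 weeks. The lymphocyte markers Ptprc (-0.17), Cd79a (-0.08) and Lck (-0.10) did not pass. Of genes chosen after their values were seen, the cytotoxic lymphocyte gene Nkg7 rose by 0.80 (adjusted p = 3.92e-06) and Rn45s by 2.23. The actin gene Actb (-1.27, adjusted p = 1.34e-08) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (-0.996, adjusted p = 5.86e-10) fell.

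**Figure D4:**
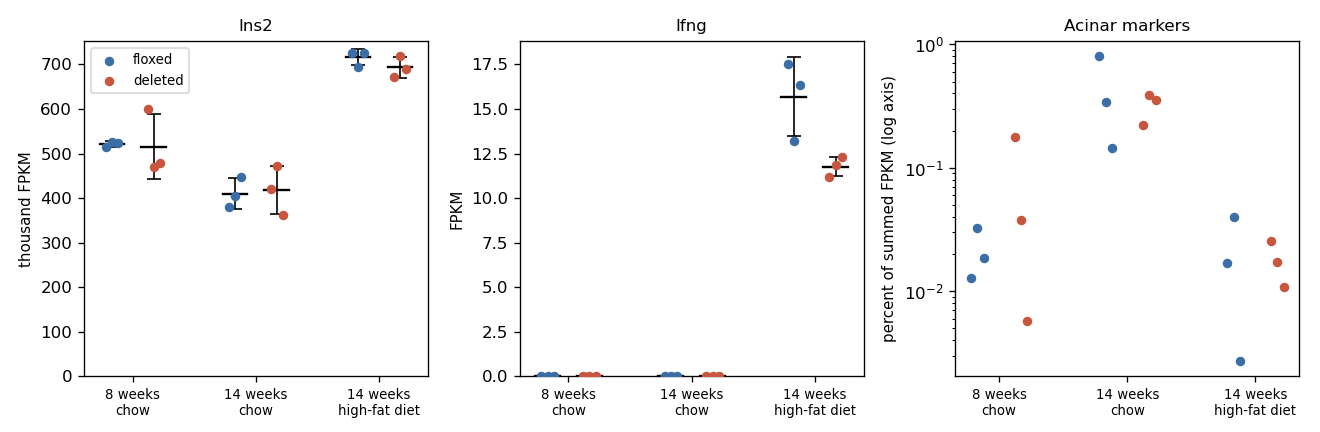
Ins2 (FPKM, scaled as its axis states), Ifng (FPKM) and acinar marker transcripts (% of summed FPKM, log axis) on the y axes, by genotype and condition on the x axis; points are libraries, and bars in the Ins2 and Ifng panels are mean ± SD of 3. Ifng lies at 0 in all 12 chow libraries and between 11.2 and 17.5 FPKM on the high-fat diet, while acinar markers are highest at 14 weeks on chow.

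By group over both genotypes, 15 of 18 oxidative stress genes rose (15 rose and 2 fell adjusted over the list alone), such as Srxn1 (0.67). Likewise 10 of 18 fatty acid oxidation genes rose, the same adjusted over the list alone, such as Cpt1a (0.75), both lists with adjusted p = 0.0171 with an estimated correlation. Ribosomal protein genes rose at 21 of 25 (0.323 with an estimated correlation) and oxidative phosphorylation genes at 13 of 26 (0.437), the latter call ending with quantile normalization. All 23 acinar markers fell (0.317), led by Reg1 (-4.53) and Pnlip (-4.51), as the acinar share of summed FPKM went from 0.427% ± 0.336 to 0.0198% ± 0.0187 in floxed and from 0.321% ± 0.0878 to 0.0180% ± 0.00742 in deleted islets. Falls were also called for fibroblast markers (8 of 10, with 1 higher, the matrix gene Mgp at 0.97; 0.323) and extracellular matrix genes (9 of 20; 0.323), as well as for macrophage markers (7 of 12; 0.0832). They were called too for endothelial markers (6 of 13; 0.323), duct markers (5 of 7; 0.116), disallowed genes (6 of 11; 0.317) and erythroid markers (3 of 4; 0.0738). The other large rises were those of Gm20594 (1.54) and Eml2 (1.34). In all 2202 genes rose and 2034 fell. With the acinar covariate 1632 passed, of which 1493 were shared and 1492 of those in the same direction, and the calls of Eml2, Reg1, Pnlip and Mgp ended. Quantile normalization ended the calls of Ins1 and Ins2. A mean of at least 5 FPKM ended the duct and extracellular matrix calls, and the disallowed call ended without replicate 1 of the deleted chow group. The diet effects in floxed and deleted islets shared 656 higher genes where 166 would be shared by chance and 403 lower genes where 97.6 would be, with 47 called in opposite directions. They had r = 0.628 (rho = 0.527) across genes, which are not independent replicates and share no libraries here.

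Whether the diet acted differently by genotype was tested as the genotype by diet interaction at 14 weeks, in which positive values mean a higher response to the diet in deleted islets. Sst (1.23, SE 0.142, adjusted p = 4.69e-05), Slc2a2 (1.05, adjusted p = 9.78e-05), Gcg (0.96, adjusted p = 0.00405) and Pdx1 (0.57, adjusted p = 0.0139) passed with positive interactions over 3 libraries in each of 4 groups. Ins1 (0.32) and Ins2 (-0.07) did not pass. The mitotic gene Ube2c (-1.85) and the hemoglobin gene Hbb-b1 (-2.50) had negative interactions, as did Necab2 (-1.74), Otoa (-1.69), Tmem37 (-1.65), Nupr1 (-1.60), Insl6 (-1.58), the ER degradation gene Derl3 (-1.52), 1190002F15Rik (-1.65) and Dapl1 (-1.51). The largest positive interactions were those of Nnat (1.58), the secretin gene Sct (1.57), Smim24 (1.45), Cyr61 (1.37), Ugt2b35 (1.34), Pcsk6 (1.30), Gfra3 (1.29), Cyp1a1 (1.28) and Rbp4 (1.26). Beta cell identity genes had a positive interaction at 7 of 24 members, 11 adjusted over the list alone (adjusted p = 0.0181 with an estimated correlation). Delta and PP cell markers had one at 3 of 5, 4 adjusted over the list alone (0.0452). Cell cycle genes had a negative interaction at 5 of 14, 7 adjusted over the list alone (0.0181), such as Birc5 (-1.50) and Ccnb1 (-1.09), and erythroid markers at 2 of 4, 3 adjusted over the list alone (0.0181). Ccnb1 passed the filter only through the floxed high-fat diet libraries. The alpha cell (3 positive and 1 negative of 7; 5 and 1 adjusted over the list alone; 0.312) and oxidative stress lists (3 of 18 positive; 5 positive and 1 negative adjusted over the list alone; 0.312) were called higher only with the preset correlation. Both calls ended with quantile normalization, as did that of Gcg, and the call of Cyr61 ended with no filter. A mean of at least 5 FPKM ended the alpha cell, oxidative stress and cell cycle list calls. The oxidative stress call also ended without replicate 3 of either chow group or replicate 1 of the deleted high-fat diet group. Of 432 genes, 174 had positive and 258 negative interactions, and 778 passed with sample quality weights. The count was 257 and 277 without replicates 3 and 2 of the floxed high-fat diet group, and 268 and 278 without replicates 1 and 2 of the floxed chow group.

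Islets of 14 weeks were compared with islets of 8 weeks on chow to describe age. In floxed islets, macrophage transcripts rose with age and Slc2a2 fell. The complement genes C1qb and C1qc, made by macrophages, rose by 1.06 (SE 0.105, adjusted p = 7.68e-06, n = 3 against 3) and 0.90, Fcer1g by 0.93 and Tyrobp by 0.79. In all 10 of 12 macrophage markers rose, 11 adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 3.64e-04). Slc2a2 fell by 0.55 (adjusted p = 0.00174), while Ins2 was at -0.35 (adjusted p = 0.0505), Ins1 at -0.32 and Gcg at 0.35. Acinar markers made up 0.0214% ± 0.0102 of summed FPKM at 8 weeks and 0.427% ± 0.336 at 14 weeks (mean ± SD, n = 3). Exocrine genes such as Cel (4.41), Cela3b (4.04), Klk1 (3.59) and Gp2 (3.56) had the largest rises, with Reg3b (3.06) and Pdia2 (2.56). The largest falls were those of Erdr1 (-1.51), the histone gene Hist1h3e (-0.88), Mtag2 (-0.85), Tceal7 (-0.77), the receptor gene Cntfr (-0.74), G530011O06Rik (-0.73), Ube2t (-0.71), Galnt9 (-0.68), 8430408G22Rik (-0.62) and Akr1c19 (-0.62).

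Beside the acinar rise in floxed islets, 8 of 23 acinar markers passed, 23 adjusted over the list alone (adjusted p = 0.0697 with an estimated correlation). Duct markers rose at 4 of 7, such as Muc1 (1.23; 5 adjusted over the list alone; 0.0162), and endothelial markers at 3 of 13, such as Egfl7 (1.31; 7; 0.0459). Rises were also seen for erythroid markers at 2 of 4, such as Hba-a1 (2.22; 3; 0.0284) and inflammatory genes at 4 of 16, such as Ptgs2 (0.68; 6; 0.0493). Insulin granule genes fell at 3 of 24 and rose at 1 (8 and 2 adjusted over the list alone; 0.0422), with the synaptic GTPase gene Rab3a at -0.30 and chromogranin B, Chgb, at 0.57. The other lists called with the preset correlation were, lower, beta cell identity (0.0592 with an estimated correlation) and, higher, extracellular matrix (0.0838), interferon (0.0673), immediate early (0.0673), fibroblast (0.158), cholesterol synthesis (0.0673), disallowed (0.0620), Notch (0.0790) and delta and PP cell genes (0.298). Of 508 genes 392 rose and 116 fell. With sample quality weights 963 passed, 232 and 245 without replicates 2 and 3 of the 14-week group, and 260 without replicate 1 of the 8-week group. With the acinar covariate 346 genes passed, 244 of them shared and in the same direction, and the calls of the insulin granule and acinar lists, Erdr1, Krt19 and Rab3a ended, as did those of Cel, Cela3b, Klk1, Gp2, Reg3b, Pdia2 and the named largest falls except 8430408G22Rik and Akr1c19. With no filter the calls of Cel, Cela3b, Hist1h3e, Mtag2, Cntfr, Ube2t and Galnt9 ended, and with a pseudocount of 0.1 those of Cel, Cela3b, Klk1, Hist1h3e and Mtag2. With only these groups in the fit the calls of the 6 named largest rises and of Erdr1, Mtag2, Cntfr, Ube2t and Krt19 ended, and with quantile normalization that of Chgb. Requiring a mean of at least 5 FPKM left 4 inflammatory genes with a median of -0.08 and ended the Notch call.

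In deleted islets, the hormone genes moved with age in opposite directions. Ppy fell by 2.24 (SE 0.450, adjusted p = 0.0204, n = 3 against 3) and Pyy fell by 0.77 (adjusted p = 0.0214). Gcg rose by 0.76 (adjusted p = 0.00142), Ins1 fell by 0.37 (adjusted p = 0.0397) and Slc2a2 fell by 0.37 (adjusted p = 0.0328). Erdr1 rose by 1.45, Fbp1 by 1.18 and the endothelial gene Egfl7 by 1.16. Rises were also those of the acinar genes Spink1 (2.97), Gp2 (2.95) and Reg3b (2.54), the duct keratin gene Krt19 (1.56) and the hemoglobin genes Hbb-b1 (1.79) and Hba-a1 (1.66). Ugt2b35 (-1.32), Fxyd3 (-1.01), Folr1 (-0.96), Cyp1a1 (-0.86), the interleukin gene Il1b (-0.83), Ugt2b36 (-0.79), Igf2bp2 (-0.76) and Tspan8 (-0.76) fell. Of 7 alpha cell markers 3 rose (5 adjusted over the list alone; adjusted p = 0.0654 with an estimated correlation). Of 23 acinar markers 2 rose (16 adjusted over the list alone; 0.231). Their share went from 0.0734% ± 0.0908 to 0.321% ± 0.0878 of summed FPKM (mean ± SD, n = 3). The other lists called with the preset correlation were, higher, macrophage (0.0590 with an estimated correlation), erythroid (0.0590), cholesterol synthesis (0.133), duct (0.151) and glycolysis genes (0.684) and, lower, beta cell identity (0.231) and oxidative stress genes (0.226). Of 356 genes 287 rose and 69 fell. With sample quality weights 1032 passed, 85 with only these groups in the fit, and 217 with the acinar covariate. The count was 149 and 202 without replicates 1 and 3 of the 14-week group, and 200 and 222 without replicates 1 and 2 of the 8-week group. The calls of Ppy, Pyy, Slc2a2, Ins1, Spink1, Gp2, Reg3b, Fxyd3, Il1b and Tspan8 ended with only these groups in the fit and with the acinar covariate. With the former those of Gcg, Fbp1, Folr1 and Ugt2b36 ended too, and with the latter those of Hba-a1 and Igf2bp2. The calls of Ins1, Slc2a2 and Il1b ended with no filter, those of Spink1, Gp2, Hbb-b1 and Hba-a1 with a pseudocount of 0.1 and those of Pyy and Reg3b with quantile normalization. Ppy no longer passed without replicate 1 or 3 at 14 weeks or 1 or 2 at 8 weeks, and quantile normalization turned Ins1 to 0.28.

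Averaged over both genotypes, older islets held more macrophage and exocrine transcripts and less Slc2a2 and insulin transcript. Slc2a2 fell by 0.46 (SE 0.0652, adjusted p = 1.50e-04, 6 libraries against 6). Ins1 fell by 0.34 (adjusted p = 0.00336), Ins2 fell by 0.32 (adjusted p = 0.00619; its share of summed FPKM was 47.1% ± 0.175 and 41.4% ± 1.17 in floxed and 45.5% ± 2.34 and 42.1% ± 1.82 in deleted islets), Pdx1 fell by 0.23 (adjusted p = 0.0254) and Gcg rose by 0.56 (adjusted p = 3.93e-04). Macrophage markers rose at 11 of 12, the same adjusted over the list alone (adjusted p = 9.89e-04 with an estimated correlation) and duct markers at 5 of 7 (6 adjusted over the list alone; 0.0181). Erythroid markers rose at 3 of 4 (0.0181) and acinar markers at 19 of 23 (23 adjusted over the list alone; 0.0901), led by Ctrb1 (3.97), Prss2 (3.87) and Sycn (3.55). Beta cell identity genes fell at 8 of 24 and rose at 1 (12 and 1 adjusted over the list alone; 0.0792). Cholesterol synthesis genes rose at 3 of 21, such as Fdps (0.56; 10 adjusted over the list alone; 0.0562). The largest falls were those of Fxyd3 (-0.79), Hist1h3e (-0.70), Syce1 (-0.60), the chemokine gene Cxcl16 (-0.58), 8430408G22Rik (-0.55), the mesothelin genes Msln (-0.52) and Mslnl (-0.51), Gm10941 (-0.52), Igf2bp2 (-0.51) and Sult1d1 (-0.50). The other lists called with the preset correlation were, higher, alpha cell (0.0848 with an estimated correlation), disallowed (0.115), extracellular matrix (0.357), fibroblast (0.344), interferon (0.229), and also endothelial (0.271), immediate early (0.271), glycolysis (0.548) and cell cycle genes (0.229) and, lower, insulin granule (0.0792) and oxidative stress genes (0.161). Of 964 genes 661 rose and 303 fell. With sample quality weights 1699 passed, 639 without replicate 2 of the floxed 14-week group and 387 with the acinar covariate, 306 of them shared and in the same direction. That covariate ended the calls of Ins1, Ins2, Pdx1, Ctrb1, Fxyd3, Hist1h3e, Syce1, Gm10941, Igf2bp2 and Sult1d1 and turned Prss2 to -0.35 and Sycn to -0.45. Quantile normalization ended the call of Ins2 and turned Ins1 to 0.14, and with only these groups in the fit the calls of Pdx1 and Sycn ended. The calls of the cell cycle, glycolysis and insulin granule lists ended with the acinar covariate and with a mean of at least 5 FPKM, which also ended the extracellular matrix and interferon calls. The acinar call ended with the covariate. The age effects in floxed and deleted islets shared 105 higher genes where 9.20 would be shared by chance and 17 lower genes where 0.654 would be, with 2 called in opposite directions. They had r = 0.554 (rho = 0.305) across genes.

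The genotype by age interaction on chow asked whether age acted differently in deleted islets, with positive values for a higher change with age in deleted islets. Erdr1, which fell with age in floxed and rose in deleted islets, had an interaction of 2.96 (SE 0.370, adjusted p = 0.00734, 3 libraries in each of 4 groups). The other positive interactions among named genes were those of Nptxr (1.51), G530011O06Rik (1.15), Mfap2 (1.05), Entpd2 (0.68) and Yipf2 (0.49). Among the negative interactions were those of Ugt2b35 (-1.46), Klhl6 (-1.07) and the circadian clock gene Arntl (-1.05). Further ones were those of Ctla2a (-1.04), the membrane linker gene Msn (-1.01), Ppap2a (-0.94), the MHC class II gene H2-Aa (-0.94), the kinase gene Sgk1 (-0.87) and the matrix gene Thbs1 (-0.86). Of 12 lists called, the macrophage markers (3 of 12 lower adjusted over the list alone; adjusted p = 0.0119 with an estimated correlation), inflammatory genes (5 of 16; 0.0119) and endothelial markers (7 of 13; 0.0455) were lower also with an estimated correlation. No member of these passed over all genes. The others, lower except for alpha cell markers (0.226 with an estimated correlation), were extracellular matrix (0.133), immediate early (0.108, with Dusp1 at -0.50), interferon (0.185), delta and PP cell (0.108), fibroblast (0.331), Notch (0.108), acinar (0.790) and duct genes (0.189). The acinar median was 0.0113 without replicate 1 of the deleted 8-week group, which held the highest acinar share at that age. Of 24 genes 6 had positive and 18 negative interactions, and of the named ones the calls of Erdr1, Ugt2b35 and Ppap2a held with no filter on low values. The count was 3 with no filter on low values, 182 with sample quality weights, 14 with only these groups in the fit and 45 with the acinar covariate. Without floxed 8-week replicate 1 or 3 it was 4 or 12, without floxed 14-week replicate 2 or 3 it was 8 or 12, and without deleted 14-week replicate 3 it was 7. Without deleted 8-week replicate 1, 2 or 3 it was 41, 11 or 10, and without deleted high-fat diet replicate 1 or 2 it was 15 or 14.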

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

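The tests of explanations and the counts over other splits of the libraries in this part were chosen only after the results were seen, whereas the interaction tests were planned. The interactions given for genes and lists are differences between groups by a test of the interaction itself, while counts of genes within a condition, and the values set beside them, come from separate comparisons.

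The genotype effect differed between diets at 432 genes. Interactions were positive for Sst (1.23), Slc2a2 (1.05), Gcg (0.96), Pdx1 (0.57), Nnat (1.58), Sct (1.57), Smim24 (1.45), Cyr61 (1.37), Ugt2b35 (1.34), Pcsk6 (1.30), Gfra3 (1.29), Cyp1a1 (1.28) and Rbp4 (1.26). They were negative for Hbb-b1 (-2.50), Ube2c (-1.85), Necab2 (-1.74), Otoa (-1.69), 1190002F15Rik (-1.65), Tmem37 (-1.65), Nupr1 (-1.60), Insl6 (-1.58), Derl3 (-1.52) and Dapl1 (-1.51). List medians were 0.31 for beta cell identity, 0.77 for alpha cell, 1.11 for delta and PP cell, -1.47 for erythroid, -0.47 for cell cycle and 0.12 for oxidative stress genes. Of 100 splits of the libraries, 1, the real one, gave as many as 432 genes, and the highest other gave 398. The splits exchanged genotype within each diet, which removes every genotype effect and not the interaction alone. They therefore cannot decide whether chance gave the count of interactions.

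More genes differed between genotypes on the high-fat diet (1312) than in either chow comparison (67 and 14). Exocrine carry-over as the whole cause is argued against, since 1348 genes passed with the acinar marker mean as a covariate, 1258 of them shared and in the same direction. A lower share of non-endocrine cells as the whole cause of the rises is argued against, since it would move the beta cell genes alike, but 16 of 23 members of the beta cell list lay above Ins2 by more than 2 SE, all set against that 1 gene. That SE treats each member and Ins2 as independent although both come from the same libraries. The comparison does not address shares among the endocrine cells. The same lower share of every non-endocrine cell type is argued against for the falls: endothelial less macrophage markers differed by -0.31 between genotypes (SE 0.0510, n = 3 against 3). This pair was picked for having the smallest SEs of the non-endocrine lists in these same libraries, so its SE may be too small. A lower share of endothelial or fibroblast cells alone (medians -0.41 and -0.60, against -0.03 for macrophage, 0.13 for acinar and 0.02 for duct markers) stays open. An effect of the deletion that appears under the diet may also hold and was not tested apart from the interaction. The 10 splits of 3 against 3 libraries on the high-fat diet are too few for a share under 0.05; the real split gave 1312 genes and the highest other gave 1.

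The genotype effect differed between ages on chow at 24 genes. Interactions were positive for Erdr1 (2.96), Nptxr (1.51), G530011O06Rik (1.15), Mfap2 (1.05), Entpd2 (0.68) and Yipf2 (0.49) and negative for Ugt2b35 (-1.46), Klhl6 (-1.07), Arntl (-1.05), Ctla2a (-1.04), Msn (-1.01), Ppap2a (-0.94), H2-Aa (-0.94), Sgk1 (-0.87) and Thbs1 (-0.86). List medians were 0.33 for alpha cell, -0.37 for delta and PP cell, -0.88 for acinar, -0.57 for duct, -0.45 for endothelial, -0.36 for fibroblast, -0.39 for macrophage, -0.45 for immediate early, -0.34 for interferon, -0.58 for inflammatory, -0.26 for Notch and -0.47 for extracellular matrix genes. Of 100 splits 3 gave as many as 24 genes, the real one included, and another split gave 59. These splits exchanged genotype within each age, so they do not test the interaction alone, and chance is not excluded.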

How the results depend on the processing

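No alternative was added after the data were seen, and the cause of a change was not tested unless stated. With no filter, 25 genes passed between genotypes at 8 weeks and 3 in the age interaction; with a mean of at least 5 FPKM, 25 between genotypes at 14 weeks on chow, and the inflammatory list in older floxed islets, left with 4 genes, turned to -0.0756. Quantile normalization gave 27 genes at 14 weeks on chow and turned Ins1 with age to 0.28 in deleted islets and 0.14 over both genotypes. That setting assigns values by rank alone, so changes of the most abundant genes depend only on their ranks. Sample quality weights gave 406, 114 and 906 genes between genotypes at 8 weeks, at 14 weeks on chow and over the conditions, 2834 for the diet in deleted islets, 963, 1032 and 1699 for age in floxed, deleted and both, and 778 and 182 for the diet and age interactions, and Cdh13 at 14 weeks on chow was at -0.77 and passed. With only the groups compared, 44 and 2 genes passed between genotypes at 8 and 14 weeks on chow, 85 for age in deleted islets and 14 in the age interaction. With the replicate block, 8 genes passed at 14 weeks on chow and 15 in the age interaction; the libraries were not treated as paired by number, since in 0 of 7 pairs of groups were all 3 correlations over 0.1, although in 2 of the 7 each library correlated best with the one of its own number (range -0.16 to 0.17). With the acinar covariate, 1807, 761 and 1632 genes passed for the diet in floxed, deleted and both, 217 and 387 for age in deleted and both, and 45 in the age interaction. It turned the diet effect of Cela2a to 1.38, Pnlip to 0.11 and Prss2 to 0.67 in floxed islets, of Ctrb1 to 0.30 in deleted islets, of Try4 to 0.0921, Prss2 to 0.62, Try5 to 0.0985, Ctrb1 to 0.0827 and Cela2a to 1.66 over both, and the age effect of Prss2 to -0.35 and Sycn to -0.45, as acinar genes share the covariate.

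Leaving out each library in turn gave 16 to 168, 3 to 30, 820 to 1568 and 298 to 479 genes between genotypes at 8 weeks, at 14 weeks on chow, on the high-fat diet and over the conditions. It gave 2585 to 3680, 1159 to 2082 and 3686 to 4436 genes for the diet in floxed, deleted and both, 232 to 636, 149 to 399 and 639 to 959 for age, and 257 to 519 and 4 to 41 for the diet and age interactions. Cdh13 ranged from -0.59 to -0.37, -0.87 to -0.68, -0.86 to -0.59 and, over the conditions, -0.72 to -0.61. At 8 weeks between genotypes the acinar list ranged from -0.0874 to 1.81 and the ribosomal list from -0.0246 to 0.118, and in the age interaction the acinar list ranged from -1.84 to 0.0113. Of 554 named gene results called, 295 were called in every alternative that tested the gene. Among the alternatives that kept all libraries, 315 were called in every one that tested the gene. Low genes dropped by the stricter filter on mean FPKM were not tested there, so these counts do not cover them in that setting. Of the list calls, 25 held with an estimated correlation and 121 did not. The number of fragments per library is unknown, which leaves the error of genes near 1 FPKM unmeasured.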

Other observations

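The tests of explanations in this part, the counts over other splits and the genes named here outside the naming rule were chosen only after the results were seen.

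Clock genes and genes induced by low oxygen were followed without a fixed list and were not tested as groups, and the time of collection was not analysed here. Between genotypes at 8 weeks Arntl (0.61, adjusted p = 0.0292) and Dbp (-0.55, adjusted p = 0.0274) passed, and Per3 (-0.37) and Tef (-0.30) did not. At 14 weeks on chow Arntl (-0.45), Dbp (0.09), Per3 (0.09) and Tef (0.09) did not pass. On the high-fat diet Tef (0.38, adjusted p = 0.0132) and Per3 (0.31, adjusted p = 0.0370) passed, and Arntl (-0.25) and Dbp (0.00328) did not. Over the mean of the 3 conditions Ankrd37 (-0.95), P4ha1 (-0.55), Bnip3 (-0.46, adjusted p = 0.0101), Mif (-0.44, adjusted p = 0.00359) and Pdk1 (-0.37, adjusted p = 0.0157) passed, and Vegfa (-0.09, adjusted p = 0.416) did not.

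Ide and Fgfbp3 were lower in deleted libraries in all 3 conditions. Loss of the whole interval from Fgfbp3 to Ide is argued against, since the 3 genes between had a median of -0.13 over the conditions. The genes between cannot address separate changes at Fgfbp3 and at Ide, in either line of mice. Of these 3, Btaf1, which lies next to Fgfbp3, was nevertheless lower on chow. It was at -0.49 at 8 weeks (limma adjusted p = 0.0375), -0.49 at 14 weeks on chow and -0.09 on the high-fat diet. The fall of Ide was of like size on both diets, with an interaction of -0.0130. This restates the falls for which Ide was followed and is not a separate test. An effect of the deletion that is the same in all conditions, or a variant of the background, may remain for this pair on chromosome 19, with Cdh13 on chromosome 8, and the design does not separate them. Among genes without overlap between genotypes in any condition, Adra2a (-0.32), Ldb1 (-0.16) and Got1 (0.10, not called) also lie on chromosome 19. Hhex, beyond Ide, was at -0.05 and -0.13 at 8 and 14 weeks on chow and 0.98 on the high-fat diet. Exoc6, beyond Hhex, and Tnks2, before Fgfbp3, did not pass. Whether these genes share a cause with the pair was not tested.

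Cytotoxic lymphocyte transcripts were listed at 0 in the 12 chow libraries and above 0 in the 6 high-fat diet libraries. More lymphocytes of all kinds stays open, since 0 of 3 tested lymphocyte markers rose but most members of that list were too low to test, and Nkg7, outside the list, rose by 0.80. Carry-over in 1 fixed mixture from another library also stays open: the ratio of Ifng to Gzmb spanned 1.02 to 2.77 in the 6 libraries, 2.72 times between the highest and the lowest. An effect of the diet cannot be told apart from a difference in handling between the diet groups, since all 6 libraries share the diet. Between the diets Actb was at -1.27, Lars2 at -0.996 and Rn45s at 2.23.

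For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each, the real split was the 1 with as many genes: 67 genes at 8 weeks between genotypes against a highest other of 0, 14 against 3 at 14 weeks on chow, 3486 against 2 for the diet in floxed and 1830 against 0 in deleted islets, and 508 against 1 for age in floxed and 356 against 8 in deleted islets. Over 100 splits, only the real one gave as many genes for the diet over both genotypes (1 split, 4236 genes, highest other 1731). The same held for age over both genotypes (1 split, 964 genes, highest other 69). Both shares are under 0.05, but the splits treat the libraries as independent, which the labels do not state. For genotype over the 3 conditions 2 of 100 splits gave as many as 442 genes, the real one included. That share is under 0.05, but the other split gave 514, so the number of genes does not by itself exclude chance.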
